A study of Pseudomonas protegens with 6 samples.

How the data were processed

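The data are 6 RNA-seq libraries of Pseudomonas protegens H78, 3 of the wild type and 3 of the rpoN deletion mutant, made from total RNA after rRNA removal and sequenced on the BGISEQ-500. The submitters' processing notes name HISAT, Bowtie2 and RSEM, without versions or roles. The genome build, the annotation and the strandedness of the libraries are not given in the sources used here, so values of overlapping or antisense genes are uncertain. The deposited table gives one FPKM value per gene and library (fragments per kilobase of gene, scaled to mapped reads, made by the authors), with gene coordinates, a symbol for 2155 of 6290 genes and a product name; 6288 are coding sequences and 2 are other RNAs. Symbols ending in _1 or _2 are the table's own numbering of genes that share a name. The authors also gave a log2 ratio of mutant over wild type, which was recomputed from the group means of FPKM within 0.027, and a probability score between 0 and 1 whose method is not given in the sources used here. Neither was used in a test. Beside them, all 1325 changed genes had the sign of the deposited log2 ratio, which is no separate check, since that ratio comes from the same FPKM values. Their median deposited probability was 0.92 (lowest 0.18), against 0.37 for other genes.

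FPKM values are already scaled for gene length and library size, and no counts are in the table. Reads estimated from them served to describe depth and the reads behind a value. Methods for counts, planned for the case of deposited counts, were not run. Low FPKM values, multiplied by the gene length less 36.5 bp, were multiples of 1 step per library, and the depth was worked out from that step. Below 60 estimated reads, 98.9% to 99.7% of values per library were then within 0.15 of a whole number. In 9 genes, at least 1 library was listed at 0. The 10 most abundant genes took 8.3% to 10.2% of estimated reads per library.

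Values were put on the log2(FPKM + 1) scale without further scaling. Genes with a mean of at least 1 FPKM were kept, which removed none of the 6290. The genotypes were compared with limma 3.58.1 in R 4.3.3 (limma-trend, robust), with Benjamini-Hochberg adjustment over all genes tested. A gene was called when its adjusted p was under 0.05 and its absolute log2 fold change was at least 1. A fold change on this scale understates the change of genes with low values. Of all genes, 2953 had an unadjusted p under 0.05. The spread within groups (median SD of log2 values) was 0.31 in the wild type and 0.22 in the mutant. The same steps were tested on simulated data of the same size: 82% of genes with a log2 change of 1.5 and 99% of genes with a log2 change of 3 were called, with 4 false calls. Each change was given to 100 genes, the widest spreads were capped, and genes varied independently. The error in the real libraries, where genes vary together, may therefore differ. In 20 draws of 32 simulated lists of 20 genes that varied independently, the shifted list was called in 20 of 20 draws, against 0 of 620 lists without a shift; genes that vary together between libraries were not simulated.

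There were 32 gene lists, with membership by symbol, or by product name where a gene has no symbol; they cover the rpoN region, motility, surface and secretion, antibiotics, iron, regulators, nitrogen, sulfur, carbon, respiration, ribosomal proteins, stress and prophages. The 30 lists with at least 4 members were tested with limma's camera with its preset correlation of 0.01, adjusted over the lists, with an estimated correlation and with fry beside it. The lists, the thresholds, the tests and the rule for named genes were fixed before the data were examined. The rule takes rpoN; in each direction, the 12 called genes with the largest fold change that have at least 10 FPKM in the higher group, groups that do not overlap and a known product; the 4 called members with a symbol and the largest change in each list that was called or had at least 2 called members; and gacA, gacS, rpoS, rpoD, phlA, pltA, prnA, hcnA, glnA, fleQ and fliC whatever their result. It gave 102 genes, of which 95 changed and 7 did not; the remaining neighbours of rpoN are named as members of a list fixed in advance.

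The alternatives tried were pseudocounts of 0.1 and 5, no filter, a minimum mean of 10 FPKM, scaling to the same median, quantile normalization, limma without trend and robust fitting, a replicate block, a test against the fold limit, list membership by symbol alone, an estimated correlation, and leaving out each library. Leaving out wild type replicate 2 and mutant replicate 1 together was added after the data were seen. A search for sigma-54 promoter motifs needs the genome sequence, which was not among the sources used here, and was not run. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.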

Results

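RNA was sequenced from Pseudomonas protegens H78, a plant-associated bacterium that makes several antibiotics, and from a mutant labelled as its rpoN deletion. The gene rpoN encodes sigma-54, an alternative sigma factor that directs RNA polymerase to its own class of promoters and needs an activator protein to start transcription. Each genotype had 3 libraries, from cells harvested in late exponential growth in KMB medium at 28 °C, at an optical density (OD600) of 4.0 to 5.0. The labels do not say whether the libraries of a genotype came from separate cultures, so p-values measure only the spread between these libraries. Expression was given as FPKM for 6290 genes. The depth worked out from the FPKM values was 6459000, 6313000 and 6538000 mapped reads in wild type replicates 1 to 3 and 5832000, 5122000 and 5436000 in mutant replicates 1 to 3. The median gene had 209 to 304 estimated reads per library. In a principal component analysis, the first component, with 76.6% of the variance, separated the genotypes. The second component, with 15.9%, set wild type replicate 2 (score -29.6) and mutant replicate 1 (score -19.4) apart from the other libraries, whose scores lay between 11.6 and 12.6. The median gene was 0.32 (log2) higher in wild type replicate 2 than in the other wild-type libraries, and 0.18 higher in mutant replicate 1 than in the other mutant libraries.

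**Figure D1:**
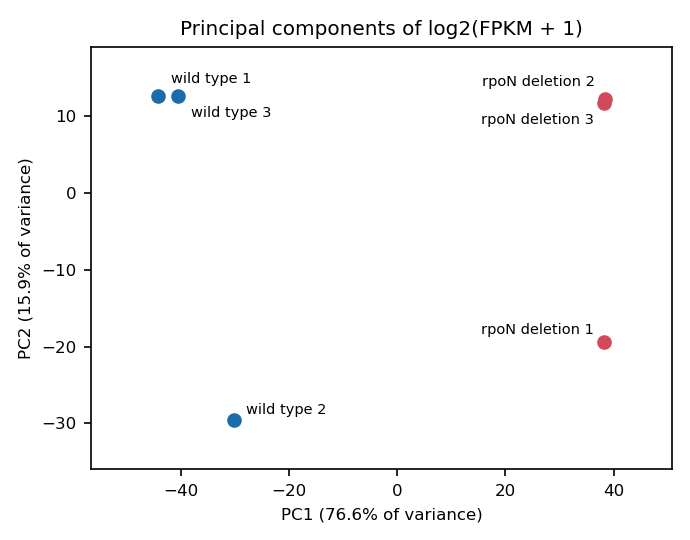
Scores of the 6 libraries on the first 2 principal components of log2(FPKM + 1), each axis with its share of the variance; each point is a library, blue for wild type and red for the rpoN deletion. The genotypes lie apart on the first axis (76.6%), and wild type replicate 2 and mutant replicate 1 lie below the other 4 libraries on the second (15.9%).

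The comparison of mutant with wild type asks which transcripts depend on sigma-54 in late exponential growth. In the mutant, 34 of 47 flagellar genes, 10 of 17 pyoluteorin genes and 20 of 57 ribosomal protein genes were lower, as were glnA (glutamine synthetase) and bdhA (3-hydroxybutyrate dehydrogenase). Of the type VI secretion genes 13 of 18 were higher, as were 14 of 17 genes for exopolysaccharides and adhesins and all 4 pyrrolnitrin genes. The widest change was that of H78_03883, a transporter gene, which fell from 1138 ± 120 FPKM (SD, n = 3) in the wild type to 4.37 ± 1.16 FPKM (SD, n = 3) in the mutant. Of 6290 genes tested, 1325 (21.1%) changed at least 2-fold at an adjusted p under 0.05 by limma, 714 higher and 611 lower in the mutant. Which direction had more genes depended on scaling: 644 were higher and 662 lower with libraries scaled to the same median, and 643 and 656 with quantile normalization. Without wild type replicate 3 the numbers were 630 and 638. Changes of at least 8-fold were seen in 20 of the higher and 76 of the lower genes. Without a minimum fold, 2347 genes changed, 1287 higher and 1060 lower. In 1309 of the 1325 genes, all mutant values lay on one side of all wild-type values, which is no separate evidence, since the calls use the same values. Over all genes tested this held for 49.2%, where chance gives 10% for a gene. Genes vary together, and any difference between the groups of libraries would raise this share. Fold changes are on the log2(FPKM + 1) scale and understate the change of genes with low values. Against the stricter test that the fold itself exceeds 2, 362 genes passed, and 62 of the 95 changed genes named here were among them. Without wild type replicate 2 and mutant replicate 1, 1501 genes changed, 1291 of them among the 1325, and 3526 changed at any fold.

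The deleted gene itself, rpoN (H78_00951, minus strand, positions 1073815 to 1075266 of the deposited coordinates), had 144 ± 11.6 FPKM (SD, n = 3) in the wild type and 24.7 ± 1.87 FPKM (SD, n = 3) in the mutant. The mutant level was 17.1% of the wild-type level, a log2 fold change of -2.50 with a standard error of 0.18 (limma adjusted p = 7.27e-06). These values rest on 1189 to 1429 estimated reads per wild-type library and 164 to 217 per mutant library, and an exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 libraries allow. Reads assigned to rpoN were thus left in every mutant library, and which part of the gene was deleted is not given in the sources used here. Of the 8 measured members of the list of rpoN and its neighbours, 2 were lower and 6 did not pass. Besides rpoN, kdsD (arabinose 5-phosphate isomerase, an enzyme for a lipopolysaccharide sugar) was lower at -1.17. Among the rest, ptsN had a log2 fold change of -0.19, lptB -0.04, lptA -0.03, lptC -0.04, kdsC 0.22 and ptsH 0.55. The list median was -0.04 (camera adjusted p = 0.3994).

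Next to H78_03883 (log2 fold change -7.75, adjusted p = 4.23e-08), which is annotated as a transporter membrane protein, bdhA fell from 2687 ± 543 to 76.2 ± 16.3 FPKM (SD, n = 3 each; -5.12). The 3-oxoacid CoA-transferase gene H78_02514 fell from 1757 ± 703 to 47.1 ± 0.452 FPKM (SD, n = 3 each; -5.12), and the fumarate hydratase gene fumC_2 from 3187 ± 723 to 72.3 ± 10.4 FPKM (SD, n = 3 each; -5.43). An outer membrane autotransporter gene, H78_03943, fell by 5.79 on the log2 scale. The other 7 of the 12 most reduced named genes were the flagellar genes fliL, flgG, fliN, flgH and flgI and the pyoluteorin genes pltA and pltL.

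Among the 12 most raised named genes, the alanine-glyoxylate transaminase gene H78_02554 rose from 30.04 ± 6.28 to 1198 ± 170 FPKM (SD, n = 3 each), a log2 fold change of 5.28 (adjusted p = 2.39e-07), and the amino acid transporter gene next to it, H78_02553, rose from 25.9 ± 2.55 to 928 ± 150 FPKM (SD, n = 3 each; 5.10). Elsewhere in the deposited coordinates, nearby genes encode an ornithine cyclodeaminase (H78_01083, 4.93), a lysine-arginine-ornithine binding protein (H78_01080, 4.11) and an FAD dependent oxidoreductase (H78_01082, 4.03). The histidine breakdown gene hutF rose from 42.4 ± 14.2 to 1006 ± 90.8 FPKM (SD, n = 3 each; 4.58) and the dihydropyrimidinase gene hydA by a log2 fold change of 3.49. The others were the acetyltransferase genes H78_05044 (5.26) and H78_04968 (3.98), the regulator gene H78_03343 (3.93), the membrane protein gene H78_04969 (3.88) and prnD (3.86).

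**Figure D2:**
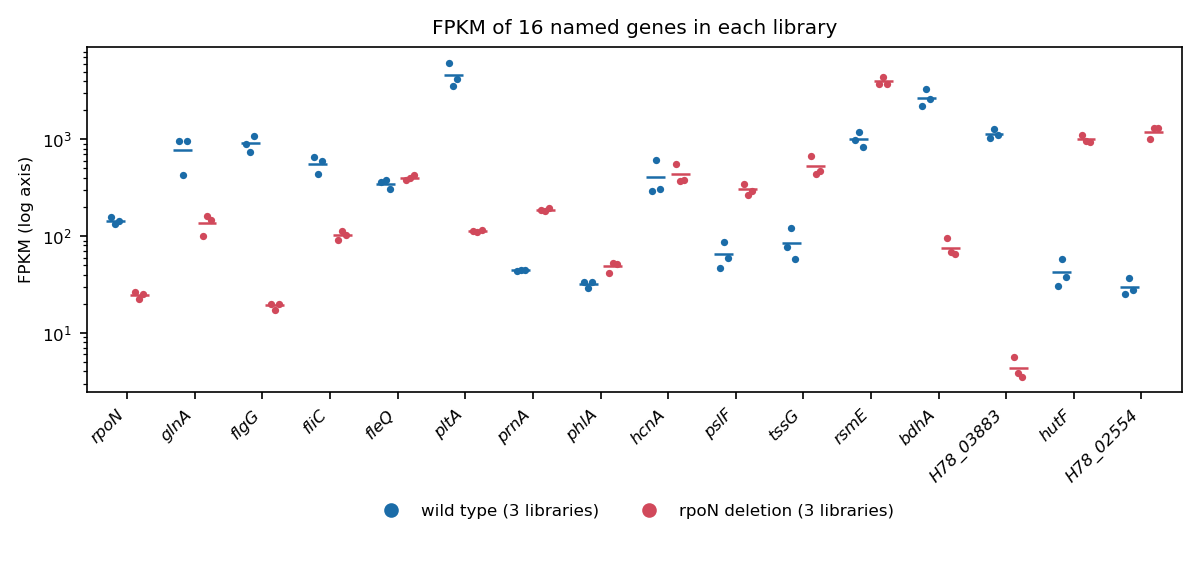
FPKM on a log axis of 16 named genes in each library (points; blue wild type, red rpoN deletion, 3 libraries each), with the group mean as a short line. In rpoN, glnA, flgG, fliC, pltA, bdhA and H78_03883 all mutant points lie below the wild-type points. In prnA, phlA, fleQ, pslF, tssG, rsmE, hutF and H78_02554 they lie above, and in hcnA they overlap. The genes phlA (log2 fold change 0.58), fleQ (0.21) and hcnA (0.16) were not called.

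Of 47 flagellar genes, 34 were lower, none was higher and 13 did not pass. Their median log2 fold change was -2.72 (camera adjusted p = 2.47e-21; adjusted p = 0.0584 with an estimated correlation). The flagellar genes with the widest falls were fliL (-5.68), flgG (from 912 ± 172 to 19.2 ± 1.54 FPKM, SD, n = 3 each; log2 fold change -5.48), fliN (-5.39), flgH (-5.37) and flgI (-5.16). The flagellin gene fliC fell from 561 ± 115 to 103 ± 11.1 FPKM (SD, n = 3 each; -2.42). The regulator gene fleR was lower at -1.23, whereas fleQ, which encodes the master regulator of flagellar genes, stood at 0.21 ± 0.18 (standard error) with an adjusted p of 0.3814. Among 53 chemotaxis genes, 9 were lower and 6 higher, with a median of 0.26 (camera adjusted p = 0.9723). With membership by gene symbol alone, the median turned to -0.50 and the list was called lower (adjusted p = 0.0283). The signalling genes cheZ (-1.98), cheY (-1.95), cheA (-1.93) and cheB (-1.45) were among those that fell.

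**Figure D3:**
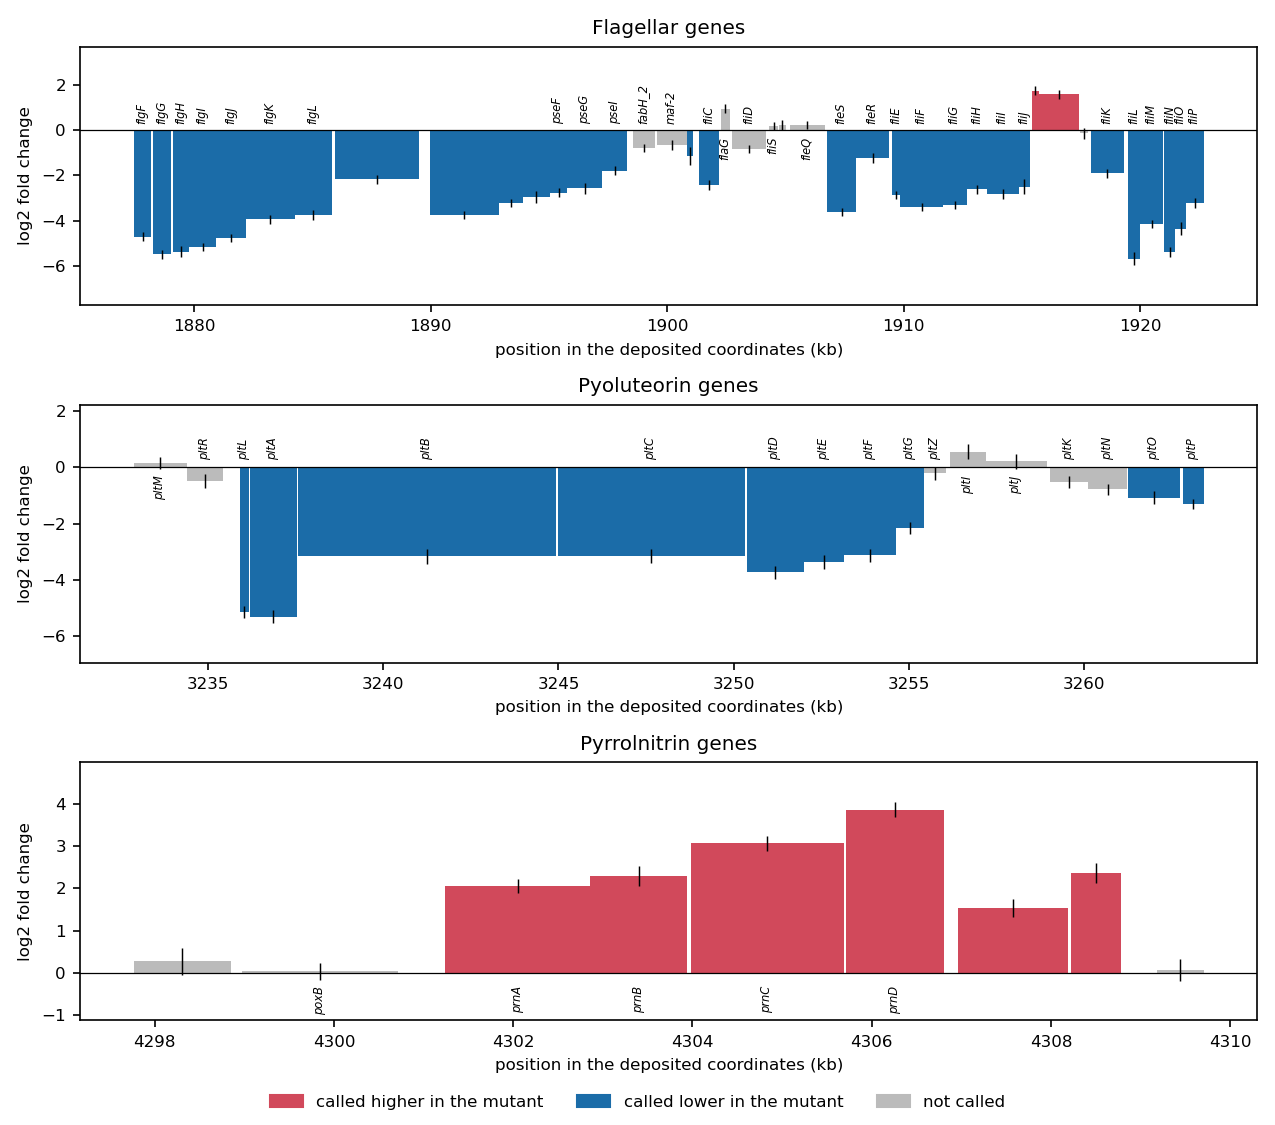
Log2 fold change (mutant over wild type) of each gene along 3 regions, drawn to scale by position in kb in the deposited coordinates; bars are genes, blue where called lower, red where called higher and grey where not called, and black lines are ± 1 standard error. Most flagellar genes and pltL to pltG lie below 0, fleQ and pltM do not, and prnA to prnD lie between 2.06 and 3.86.

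Genes for the antibiotics of this species moved in different directions. For pyoluteorin, a chlorinated polyketide, 10 of 17 genes were lower, none was higher and 7 did not pass. The pyoluteorin median was -1.30 (camera adjusted p = 1.74e-07; adjusted p = 0.324 with an estimated correlation). The halogenase gene pltA fell from 4637 ± 1372 to 113 ± 3.52 FPKM (SD, n = 3 each; log2 fold change -5.30), pltL from 8494 ± 1546 to 238 ± 21.6 FPKM (SD, n = 3 each; -5.14), and pltD (-3.73) and pltE (-3.37) fell as well. For pyrrolnitrin, a chlorinated antifungal compound made from tryptophan, all 4 genes were higher. Their median was 2.68 (camera adjusted p = 0.000108; adjusted p = 0.2141 with an estimated correlation). The gene prnD rose from 21.9 ± 1.56 to 332 ± 38.7 FPKM (SD, n = 3 each; 3.86), and prnC (3.06), prnB (2.29) and prnA (2.06) rose as well. For 2,4-diacetylphloroglucinol, an antifungal polyketide, 2 of 8 genes were higher and 6 did not pass. The median of these 8 was 0.64 (camera adjusted p = 0.0428; adjusted p = 0.5935 with an estimated correlation). These were phlD (1.25) and phlB (1.12), while phlA had 0.58 (adjusted p = 0.0406, under the fold limit). The call for phlB ended without wild type replicate 2 (0.95), without mutant replicate 2 (0.94) and with a pseudocount of 5 (0.95). The call for this list ended without wild type replicate 2 (camera adjusted p = 0.134), mutant replicate 2 (0.1072) or mutant replicate 3 (0.0664). It also ended with libraries scaled to the same median (0.0804), quantile normalization (0.1003), a minimum mean of 10 FPKM (0.0572) and a replicate block (0.068). None of the 3 hydrogen cyanide synthase genes passed (median 0.22; hcnA 0.16), and neither did any of the 3 genes of the lipopeptide orfamide (median 0.55); both lists were too small for a list test.

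In the type VI secretion system, a contractile device that injects toxins into neighbouring cells, 13 of 18 genes were higher, none was lower and 5 did not pass. The type VI median was 1.79 (camera adjusted p = 1.74e-07; adjusted p = 0.3619 with an estimated correlation). Examples are tssG, from 85.1 ± 31.8 to 525 ± 125 FPKM (SD, n = 3 each; log2 fold change 2.65), ppkA (2.48), tagF (2.48) and tagT (2.43). The type VI genes that did not pass, named after their values were seen, were H78_03022 (0.18), hcp (0.23), tssA (0.56), tssE (0.76) and tssK (0.85). Of 17 genes for exopolysaccharides and adhesins other than alginate, 14 were higher, none was lower and 3 did not pass. The exopolysaccharide median was 1.71 (camera adjusted p = 1.71e-07; adjusted p = 0.2871 with an estimated correlation). Psl genes led this list, with pslF at 64.9 ± 20.5 FPKM in the wild type and 303.5 ± 41.3 FPKM in the mutant (SD, n = 3 each), pslC at a log2 fold change of 2.11, pslH at 2.11 and pslK at 1.997. In wild type replicate 2 the medians of the type VI and exopolysaccharide lists lay 0.64 and 0.52 (log2) above the other wild-type libraries, and in mutant replicate 1 they lay 0.30 and 0.23 above the other mutant libraries. Without these 2 libraries the medians were 1.86 and 1.79. Of 29 type IV pilus genes, 10 were higher, 1 was lower and 18 did not pass. The pilus median was 0.63 (camera adjusted p = 0.0214; adjusted p = 0.7915 with an estimated correlation). This call ended with membership by symbol alone (adjusted p = 0.1541). The genes pilM (1.42), pilO_2 (1.42), pilP_1 (1.36) and pilC (1.31) were higher. Of the 10, 3 encode PilZ proteins, a domain known for binding cyclic di-GMP (H78_04572 at 2.49, H78_00988 at 1.47, H78_05560 at 1.33). These and the lower gene, H78_05517 (-1.15), were chosen after their values were seen. The call for pilP_1 ended without wild type replicate 1 (1.07, adjusted p = 0.0646) or wild type replicate 3 (1.21, adjusted p = 0.0702).

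Of 20 alginate genes, 6 were higher, none was lower and 14 did not pass. The alginate median was 0.38 and the list was not called (camera adjusted p = 0.1066). The regulators algR (1.32) and algU (1.27), the precursor enzyme gene algA (1.12) and mucB (1.03), which encodes a protein that holds AlgU in check, were among the 6. The others, chosen after their values were seen, were mucA (1.03) and an alginate lyase gene, H78_05979 (1.88), the widest rise in the list. Also chosen after their values were seen, the biosynthesis genes algD (-0.12), alg44 (0.16) and algK (0.33) were not called. The call for algA was fragile: it ended without wild type replicate 1 (1.16, adjusted p = 0.0659), wild type replicate 2 (0.76), mutant replicate 2 (1.06, adjusted p = 0.082) or mutant replicate 3 (0.98), without both libraries that stood apart (0.96), and with median scaling (1.06, adjusted p = 0.0569) or quantile normalization (1.06, adjusted p = 0.0709). That for mucB ended by falling under the fold limit without wild type replicate 1 (0.98), mutant replicate 2 (0.99) or mutant replicate 3 (0.99), and with median scaling (0.97) or quantile normalization (0.99).

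Of 34 nitrogen assimilation genes, 4 were lower, 2 higher and 28 did not pass, and the median of 0.02 (camera adjusted p = 0.5017) turned to -0.04 under median scaling and quantile normalization. Glutamine synthetase, the main enzyme for ammonium assimilation, fell: glnA went from 782 ± 310 to 136 ± 31.3 FPKM (SD, n = 3 each; log2 fold change -2.45, adjusted p = 3.68e-04), with wild type replicate 2 (424 FPKM) below the other wild-type libraries (956 and 967.5 FPKM). The glutamate dehydrogenase gene gdhA (from 743 ± 131 to 139 ± 39.1 FPKM, SD, n = 3 each; log2 fold change -2.44) and the urease gene ureA (-1.27) were also lower and xdhA, for purine breakdown, was higher (1.82). The remaining calls, chosen after their values were seen, were glnA_1 (-1.19) and codB (1.04). Also chosen after their values were seen, the urease genes ureB (-0.10) and ureC (0.02), amtB (-0.24) and glnK (0.05) did not pass. Of 88 genes of amino acid uptake and breakdown, 14 were higher, 12 lower and 62 did not pass (median 0.16, camera adjusted p = 0.9723). The glycine cleavage genes gcvH (-4.10), gcvP_1 (-3.65) and gcvT_1 (-2.23) fell. A second set of glycine cleavage genes, chosen after their values were seen, did not pass: gcvP_2 had 0.85 (adjusted p = 0.0332, under the fold limit), gcvH_2 0.41 and gcvT -0.17. The gene phhA, for phenylalanine hydroxylase, rose (2.51). Of 26 genes for the use of sulfonates, sulfate esters and inorganic sulfate, 8 were lower, none was higher and 18 did not pass. The sulfur median was -0.48 (camera adjusted p = 0.000483; adjusted p = 0.5935 with an estimated correlation). They included ssuA (-1.97), msuC (-1.93), ssuC (-1.91) and tauA (-1.73), which serve sulfonate and taurine uptake and breakdown, and, chosen after its value was seen, the sulfate adenylyltransferase gene cysD (-1.41).

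Of 57 ribosomal protein genes, 20 were lower, 1 was higher and 36 did not pass. Of these, H78_01969 (not called) is annotated as a modification enzyme of a ribosomal protein, and without it the median was -0.79. The ribosomal median was -0.78 (camera adjusted p = 3.07e-07; adjusted p = 0.6666 with an estimated correlation). The genes rpmB (from 4524 ± 1673 to 843 ± 104 FPKM, SD, n = 3 each; log2 fold change -2.35), rpmG (-2.18), rpsJ (-2.07) and rpmE_2 (-1.80) fell. The only higher member, chosen after its value was seen, was H78_01343 (1.09), annotated as ribosomal protein S3. The list also differed within groups: its median was -0.66 in wild type replicate 2 against the other wild-type libraries and -0.22 in mutant replicate 1 against the other mutant libraries. Without these 2 libraries the list median was -0.90. Of 44 genes of respiration and ATP synthesis, 8 were lower, 3 higher and 33 did not pass, and the list was not called (median -0.12, camera adjusted p = 0.1805). It was called lower without wild type replicate 2 (median -0.36, adjusted p = 0.0032) and without both libraries that stood apart (-0.31, adjusted p = 0.0188). The genes ccoG_2 (-1.80), ccoN_2 (-1.59) and ccoN_1 (-1.52) of the high-affinity cbb3 oxidase fell, and cyoE_1, for a haem-modifying enzyme, rose (1.56). The other higher genes, cyoC_2 (1.24) and cyoD_2 (1.22), were chosen after their values were seen. Of 5 denitrification genes, azu (azurin, -1.82) was lower, nirK (nitrite reductase, 1.28) higher and 3 did not pass (median -0.01, camera adjusted p = 0.7822). The denitrification median turned to 0.38 without wild type replicate 3 and to 0.31 without mutant replicate 1, and the list was not called in either. Of 18 genes of the citric acid and glyoxylate cycles and of pyruvate dehydrogenase, fumC_2 (-5.43) and the pyruvate dehydrogenase gene aceE_2 (-1.53) were lower, mqo_2 (1.36) and aceA (1.22) higher and 14 did not pass (median 0.08, camera adjusted p = 0.9723). Without the 3 pyruvate dehydrogenase genes, the median was 0.15 and the list was not called either (adjusted p = 0.7292), though the test turned upward. The call for aceA, isocitrate lyase, ended without wild type replicate 2, where it fell just under the fold limit (1.0, adjusted p = 0.0039).

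Among the regulators of secondary metabolism, the Gac/Rsm list had 3 of 9 genes higher, none lower and 6 that did not pass (median 0.37, camera adjusted p = 0.2073). The RNA-binding regulator gene rsmE rose from 996 ± 178 to 3949 ± 364 FPKM (SD, n = 3 each; log2 fold change 1.998), the sensor gene retS rose by a log2 fold change of 1.62 and rsmA by 1.22. The call for rsmA ended without wild type replicate 3 (0.87) or mutant replicate 2 (1.10, adjusted p = 0.0609). The response regulator gene gacA had -0.72 (adjusted p = 0.0133, under the fold limit), its sensor gacS 0.37 (adjusted p = 0.1927), the stress sigma factor gene rpoS -0.35 (adjusted p = 0.3684) and the housekeeping sigma factor gene rpoD -0.08 (adjusted p = 0.8234; 0.05 under quantile normalization). Of 32 sigma factor genes, rpoS and rpoD among them, 2 were higher, none was lower and 30 did not pass (median -0.09, camera adjusted p = 0.3925); these were algU and, chosen after its value was seen, H78_00191 (1.32). Of 19 genes listed as activators of sigma-54 promoters, 3 were lower, 2 higher and 14 did not pass (median 0.16, camera adjusted p = 0.7282). Some, H78_03343 among them, were listed only by the product name Fis family transcriptional regulator, which does not itself state this role. The called genes were acoR (-1.36), fleR (-1.23), H78_03343 (3.93) and, chosen after their values were seen, H78_04450 (-1.65) and H78_05827 (1.495). Of 15 exoenzyme and toxin genes, 3 were lower, 2 higher and 10 did not pass (median 0.29, camera adjusted p = 0.727). The list takes in lipA by its symbol, which the table annotates as lipoyl synthase and not as an exoenzyme; it was not called (0.64), and without it the list median was 0.20. The insect toxin gene fitD (-1.28) and its regulators fitH (-2.04) and fitG (-1.56) fell, and the protease gene aprA (2.04) and, chosen after its value was seen, the chitinase gene chiC (1.23) rose.

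Of 23 pyoverdine genes, 1 was higher and 22 did not pass (median 0.16, camera adjusted p = 0.4298); it was pvdO_1 (1.006), chosen after its value was seen. Of 11 genes of the siderophore enantio-pyochelin, 2 were lower and 9 did not pass (median 0.23, camera adjusted p = 0.9723): the receptor gene fetA (-1.57) and the synthesis gene pchD (-1.08). In wild type replicate 2 the pyochelin list lay 0.79 (log2) above the other wild-type libraries and in mutant replicate 1 it lay 0.57 above the other mutant libraries. The call for pchD ended without wild type replicate 1 (-1.12, adjusted p = 0.0871), wild type replicate 2 (-0.76, adjusted p = 0.0715), mutant replicate 2 (-0.88, adjusted p = 0.1307) or mutant replicate 3 (-0.91, adjusted p = 0.1268). Of 43 iron and haem uptake genes, 3 of which are also in the pyoverdine list, 2 were lower and 41 did not pass (median 0.20, camera adjusted p = 0.9723). They were the haem oxygenase gene hemO (-1.001) and the receptor gene H78_02429 (-1.11), the latter chosen after its value was seen. At the fold limit, hemO lost its call without wild type replicate 1 (-0.99), wild type replicate 2 (-0.88), mutant replicate 2 (-0.90) or mutant replicate 3 (-0.91), and with a pseudocount of 5 (-0.98).

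In the list for the storage polyester polyhydroxyalkanoate, 5 of 11 genes were higher, none was lower and 6 did not pass. The median of all 11 was 0.92 (camera adjusted p = 0.0023; adjusted p = 0.2284 with an estimated correlation). Of the 5, phaG_1 (2.47) encodes a transacylase that supplies polyester precursors. The others, phaC (H78_02822, 1.89), phaG (H78_02818, 1.54), phaF (H78_02819, 1.53) and, chosen after its value was seen, phaD (H78_02821, 1.48), are annotated as subunits of a cation/proton antiporter that shares these symbols. Without these 4 genes, an alternative chosen after the result was seen, 1 of 7 genes was higher, the median was 0.62 and the list was not called (camera adjusted p = 0.1207). The call for the list thus rested on the antiporter genes. Of 83 prophage and tailocin genes, 11 were higher, none was lower and 72 did not pass (median 0.19, camera adjusted p = 0.1263). The prophage list was called higher without wild type replicate 1 (0.24, adjusted p = 0.0211), without mutant replicate 1 (0.28, adjusted p = 0.0095) and without both libraries that stood apart (0.30, adjusted p = 0.0213). A single gene was lower in each of 4 lists, none was higher, and each gene was chosen after its value was seen. These were H78_02707 (-1.10) among 6 genes of C4-dicarboxylate transport (median -0.39, camera adjusted p = 0.2073), acsA_2 (-1.81) among 12 of acetoin, acetate and propionate use (median 0.09, camera adjusted p = 0.5477), groL (-1.04) among 16 heat shock genes (median 0.01, or -0.04 under median scaling; camera adjusted p = 0.9526) and ahpC (-1.43) among 12 of oxidative stress defence (median -0.19, camera adjusted p = 0.3925).

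**Figure D4:**
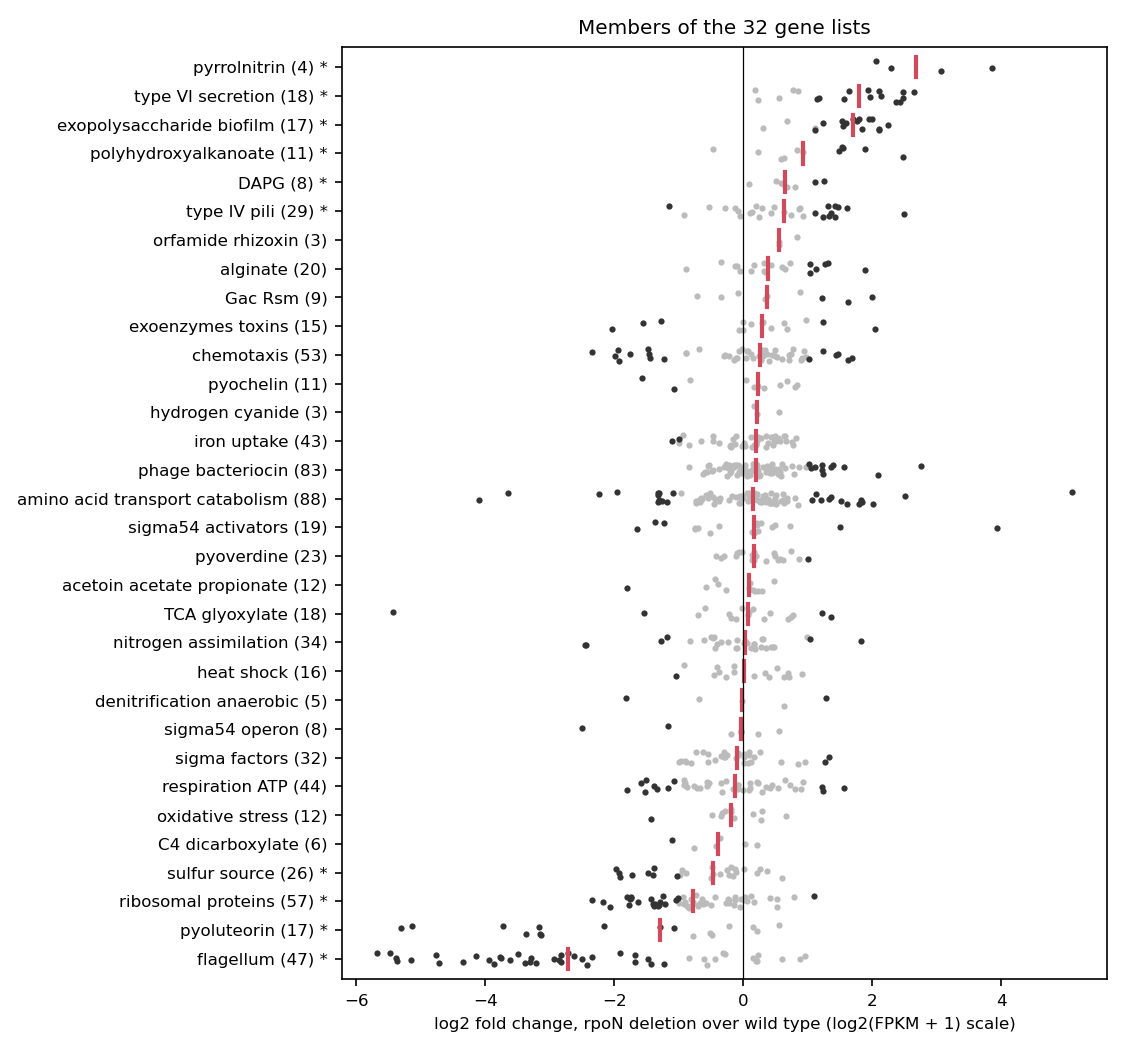
Log2 fold change (mutant over wild type, log2(FPKM + 1) scale) of each member of the 32 gene lists; points are genes, dark where called and grey where not, red bars are list medians, numbers in brackets are members tested and a star marks a list called by camera. List medians run from -2.72 (flagellum) to 2.68 (pyrrolnitrin).

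Of 30 lists tested by camera, 10 were called, or 9 with members annotated outside their list left out, the polyester list being the one lost. None kept an adjusted p under 0.05 with the correlation between genes estimated for each list, and 4 had an unadjusted p under 0.05 there. That setting also uses far fewer degrees of freedom, so the loss does not by itself show that genes varying together made the calls. The limma test fry asks whether a list's genes move and does not compare them with other genes. It gave an adjusted p under 0.05 for 14 lists in 1 direction on balance and for 30 in either direction. As all 30 lists tested passed in either direction, that result sets no list apart. Adjusted over the list alone, the numbers of higher and lower members equalled those over all genes in 31 of the 32 lists; in the exopolysaccharide list 15 were higher in place of 14. In 6 lists that were not called, the median or mean had another sign than the test. The test was downward for nitrogen assimilation (median 0.02, mean -0.14), activators of sigma-54 promoters (0.16, 0.05), pyochelin (0.23, 0.02), the citric acid and glyoxylate cycles (0.08, -0.16), acetoin, acetate and propionate use (0.09, -0.16) and heat shock (0.01, 0.04).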

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

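Leaving out wild type replicate 2 and mutant replicate 1 together, and leaving out list members annotated outside their list, were chosen after the result was seen; the other alternatives were planned. The number of genes changed (1325) ranged from 1171 with a pseudocount of 5 to 1501 without these 2 libraries, apart from single libraries left out and the test against the fold limit. Under that test 362 genes passed, 176 higher and 186 lower, because it asks for a fold significantly above 2; used for the count at any fold it also gave 362 in place of 2347, since it brings in a fold limit. Leaving out each library gave 1208 to 1548 genes changed, 623 to 927 higher, 576 to 672 lower, 1625 to 3055 at any fold, 9 to 11 lists and a log2 fold change of rpoN of -2.56 to -2.44. Without both libraries that stood apart, the count at any fold was 3526. The libraries that remained were the most alike of their groups (correlations of log2 values of 0.986 in the wild type and 0.992 in the mutant). A narrower spread within groups raises such a count, so the rise is no separate evidence of more changed genes. How much of the rise came from this was not tested. With an estimated correlation, 0 lists were called by camera, against 4 at an unadjusted p under 0.05. For the polyester list the estimate was -0.037, below the preset correlation, yet its camera adjusted p rose from 0.0023 to 0.2284. A higher correlation between genes therefore does not account for the loss of that call. The estimates were 0.027 for pyrrolnitrin and 0.038 for the flagellum, and 0.163 to 0.374 for the remaining called lists. With an estimated correlation, camera also takes its degrees of freedom from the few libraries and not from the many genes, which raises p by itself. These differences were not tested apart, so the lost calls cannot be put down to genes varying together. The chemotaxis median turned from 0.26 to -0.50 with membership by symbol alone, which leaves out members that have no symbol. Of 1616 values for 101 named genes other than rpoN, 1554 kept their side of the threshold and 62 lost the call, 33 of them against the fold limit; the sign differed in 5, all for rpoD or hcnA, which were not called. Of 538 list values, 513 kept their side, 19 lost and 5 gained a call, and 1, the chemotaxis value, turned with a call; the median had another sign in 24 more, each where the list was not called. Median scaling shared 1251 of its 1306 genes with the 1325, and quantile normalization 1243 of 1299. The median over all genes was 0.12, and 0.06 under either scaling.

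The labels do not say that replicate numbers mark pairs, and within-group deviations of libraries with the same number correlated across genes at -0.44, -0.46 and 0.37; a replicate block gave 1333 genes changed and 9 lists, ending the call for 2,4-diacetylphloroglucinol (adjusted p = 0.068). The filter on low values removed no gene, so running without it changed nothing. Alternatives planned for deposited counts were not run, as FPKM was deposited. The motif search with its 2 alternatives was not run, since no genome sequence was among the sources used here. Depth of 5122000 to 6538000 estimated reads limits genes of low level: a fold change there rests on few reads and on the pseudocount.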

Other observations

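The runs of genes, the functional classes, the splits for any fold and for gene lists, and the tests of a label swap, of depth and of leaving out 2 libraries were chosen after the result was seen. Called genes stood side by side. Over all genes, members of the lists included, there were 27 runs of at least 5 adjacent genes on the same strand called in the same direction. Of these, 16 were higher and 11 lower, and they held 204 genes. At most 2 runs arose in any of 1000 shuffles of gene order. A shuffle also separates neighbours that are transcribed together, so the excess is not particular to the deletion. Described here are the runs with no member in a list. A polyol uptake and breakdown run, mtlE to mtlZ (7 genes, positions 3608060 to 3616550), had a median log2 fold change of -4.01, with mtlF at -4.27 and mtlK at -4.26. An inositol run of 11 genes (positions 3008599 to 3021150) had a median of -2.92, with iolE at -3.46 and iolB at -3.36. A lactate run of 5 genes (positions 949354 to 956953) had a median of -2.15, with the L-lactate permease gene glcA at -3.70. The other lowered runs of this kind were 5 genes at positions 3075916 to 3081607 (median -1.71) and 5 genes from fadB1x at positions 3600871 to 3606448 (median -1.68). Next to bdhA, acsA1 (acetoacetyl-CoA synthetase) was lower at -4.70, and next to H78_02514, scoA (3-oxoacid CoA-transferase) was lower at -4.34.

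Among raised runs, 9 genes (positions 5492883 to 5505798), H78_04968 (3.98) and H78_04969 (3.88) among them, had the highest median of this kind, 2.41. Another 8 genes of a Flp-type pilus (positions 806418 to 813880), cpaB among them at 2.03, had a median of 1.97. A run of 7 type I pilus genes (positions 4676521 to 4683086) had a median of 1.96, with csuD at 2.26 and csuE at 2.03. A run of 12 genes (positions 6281523 to 6297444) had a median of 2.26; its members include H78_05733 (3.21) and H78_05736 (1.88), both annotated as cytochrome c family proteins. A run of 6 cell wall and division genes from ftsQ to murD (positions 5815049 to 5821940) had a median of 1.15. The others were 8 genes at positions 3306471 to 3315590, batA among them, and 5 genes at positions 3909051 to 3916638, each with a median of 1.74. By functional class (COG; 40 Fisher's exact tests over 5385 classified genes, which are not independent), 14 tests had an adjusted p under 0.05. Motility genes were more often lower (41 of 172, odds ratio 2.85, adjusted p = 1.09e-05) and also more often higher than other genes (29, odds ratio 1.74, adjusted p = 0.0428). Translation genes were more often lower (42 of 218, odds ratio 2.16, adjusted p = 0.000436) and less often higher (4, odds ratio 0.15, adjusted p = 1.57e-05). Signal transduction genes were more often higher (75 of 414, odds ratio 1.99, adjusted p = 2.31e-05), carbohydrate genes more often lower (48 of 290, odds ratio 1.79, adjusted p = 0.0056) and transcription genes less often lower (29 of 558, odds ratio 0.45, adjusted p = 6.7e-05); the rest of the 14 had odds ratios of 0.44 to 1.62.

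Wild type replicate 2 and mutant replicate 1 deviated from their groups in the same genes, with a correlation of deviations of 0.64 across genes, which are not independent replicates. A swap of these 2 labels is argued against, since rpoN in wild type replicate 2 was 5.06 times the highest mutant value. Depth is argued against, since wild type replicate 2 differed by -2.9% from the mean of its group's other libraries and mutant replicate 1 by 10.5%; removing trends with gene length or with expression level in 50 bins left the correlation at 0.63 and 0.62. A shared day of culture or library preparation could give such a pair but is not labelled, and the density of each culture within the range of 4.0 to 5.0 is not given in the sources used here. No biological explanation was tested, and both remain open.

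Of 57 genes listed as ribosomal proteins, 20 were lower in the mutant, 1 was higher and 36 did not pass, with a list median of -0.78 (camera adjusted p = 3.07e-07; adjusted p = 0.6666 with an estimated correlation). That short and abundant genes simply read lower in the mutant libraries is argued against: of 10000 lists matched by gene length and mean expression, 0 had a median as low, with a median of 0.17 and a lowest value of -0.54. The libraries that stood apart are argued against as the whole cause by their direction. The list median was -0.66 in wild type replicate 2 and -0.22 in mutant replicate 1 against the other libraries of their groups. The larger deviation, in the wild type, narrows the difference between genotypes. That the median was -0.90 without both libraries follows from these deviations and is not a further test. An effect of the deletion on ribosomal protein transcripts may remain as a hypothesis, but a difference in growth stage at harvest could give the same picture and was not tested, since culture densities per library are not given in the sources used here.

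With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. Of these, 1 split, the real one, gave as many genes changed (1325, highest other 0) and 1 as many at any fold (2347, highest other 0). Every other split mixed wild-type and mutant libraries within each group, so the difference between genotypes widened the spread within groups. The 0 in those splits therefore cannot tell an effect of the deletion from chance or from another difference that coincides with genotype. For gene lists, 5 of the 10 splits gave at least the 10 lists of the real split. The highest other, with 16 lists, set wild type replicates 1 and 2 and mutant replicate 1 against the rest. Every other split leaves part of the genotype difference between its groups, and camera compares a list with other genes. The number of lists therefore cannot tell an effect of the deletion from chance either.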
